A study of Mus musculus with 2 samples.

How the data were processed

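The data were 2 iCLIP libraries from mouse forebrain neurons kept in culture for 14 days in vitro (DIV), 1 made with antibodies against Rbfox1 and 1 with antibodies against the Flag epitope, which served as the control. In iCLIP, ultraviolet light joins proteins to the RNA they touch, the protein is precipitated with its RNA fragments, and reverse transcription tends to stop at the joined base, so that the start of a read marks the contact. Per the labels' protocols, the neurons received 254 nm light at 500 mJ/cm2 on ice and were opened for 1 min with 0.1% of the detergent Triton X-100 in a HEPES buffer holding NaCl at 150 mM, and the released cytoplasmic material was used for precipitation.

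The deposited files hold aligned reads, 1 per line, each with its first and last base, its strand and a further position. Per the submitters' processing notes, Bowtie and the mm9 build of the mouse genome were used. Versions, mismatch settings, the removal of PCR copies and any filter on clusters are not given in the sources used here. From the values, the further position lay 1 base upstream of the 5′ end of the read in 64820 of 64820 anti-Rbfox1 reads and 569 of 569 anti-Flag reads, and it was used as the crosslink position. No pair of reads in a library shared start, end and strand, and no cluster had a single crosslink position, so the deposited reads had been collapsed and filtered. The number of reads at a position is therefore limited by that collapse and does not count all molecules. In some blocks of the file lines, described next, no reads shared a leftmost base and strand. There a plus-strand position held 1 read, while elsewhere the number counts reads of different lengths. Reads per position and per cluster are thus not alike between blocks.

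In both files the chromosome order starts again several times, which divides the lines into 11 blocks in the anti-Rbfox1 file and 7 in the anti-Flag file. What the blocks stand for is not given in the sources used here. Blocks of the 2 libraries were matched by the reads that overlapped between them. All 141 overlapping anti-Flag reads fell into 4 pairs of blocks, called A to D here, and 0 reads overlapped more than 1 block. The pairs rested on 60 such reads in A, 71 in B, 2 in C and 8 in D, so the matches of C and D are less certain. The blocks outside these pairs held 3679 anti-Rbfox1 reads (5.68%) and 8 anti-Flag reads (1.41%).

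Reads of a library whose crosslink positions lay within 20 nt of each other on the same strand were joined into clusters. Clusters whose outer bases lay within 1000 nt of each other on the same strand were joined into stretches. Neighbours within 1000 nt were counted between the midpoints of clusters, so the counts of clusters in stretches and with neighbours can differ. Overlap between libraries meant at least 1 shared base on the same strand. Its chance level came from 100 random placements of the anti-Flag reads within 100 kb of their place on the same chromosome, without regard to transcripts. Shares were given exact Clopper-Pearson 95% intervals, and ratios of counts exact 95% intervals. Where a count was 0, 3 counts of the total were taken as the limit. These intervals and limits cover counting error only, because reads of amplified libraries are not independent molecules. Shares of clusters on each chromosome and strand were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 22 tests. With 1 library per antibody, such a test compares these libraries and not the antibodies in general, and no difference has a replicate check. To compare cluster sizes at equal reads, the anti-Rbfox1 library was thinned to 569 reads in 100 random draws and then filtered to clusters of at least 2 positions. The share of reads in each of the 10 highest anti-Rbfox1 clusters was compared between libraries by Fisher's exact test, a test added after the data were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

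The procedure was tested on simulated data. It found 500 of 500 planted clusters and 286 of 286 planted overlapping reads, where the highest random placement gave 5. The planted clusters lay far apart and the planted overlapping reads were copies of anti-Rbfox1 reads. Full recovery was therefore set by construction and checks only that the steps ran as written. With chromosome 11 tripled in the anti-Flag clusters, it called that chromosome in 100 of 100 draws and made 11 other calls.

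Transcript regions, the Rbfox sequence motif, positions within 3′ untranslated regions, genes with most binding and gene lists had been planned before the data were examined and were not analysed here, because they need a genome and annotation of the mm9 build. The annotation at hand was of GRCm38, and 6 of the 21 chromosomes held reads beyond its last annotated base, so no coordinates were set against it and no gene is named. The plan for that case was to describe strand, chromosome and clustering, and to name the 10 highest clusters of each library by position. Settings listed beforehand and based on a count or score per record were not run, since each line is a single read with neither. The alternatives that were run concerned the unit counted, the distance for merging or overlap, strand, and clusters near the other library. Others, chosen after the data were seen, concerned blocks, cluster size, neighbour distance and pairs of near-identical reads.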

Results

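Crosslinked RNA from the cytoplasmic fraction of cultured mouse forebrain neurons was sequenced after precipitation with anti-Rbfox1 or anti-Flag antibodies, with 1 library each. Rbfox1 is an RNA-binding protein of neurons known as a regulator of splicing, and the series asks where it binds RNA in the cytoplasm. The anti-Flag precipitate was the control. The anti-Rbfox1 library held 64820 deposited reads and the anti-Flag library 569. Read length had a median of 28 nt in both, with an interquartile range of 23 to 35 nt in the anti-Rbfox1 library and 21 to 36 nt in the anti-Flag library. There were no replicates, so intervals cover counting error only and the tests compare these libraries.

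The first comparison asked how many deposited reads each library held and how they were spread over the genome. The anti-Rbfox1 library held 113.9 times as many reads as the control (95% interval 104.9 to 123.9), at 47896 against 525 distinct crosslink positions. These formed 10134 clusters covering 465054 nt in the anti-Rbfox1 library and 233 clusters covering 7343 nt in the control, a 43.5-fold difference in clusters (38.2 to 49.7). The reads were not scaled to sequencing depth, since the number of reads before filtering was not used here. A filter to clusters of at least 2 positions also bears on these ratios, because it removes more of a sparse library. Of 569 anti-Rbfox1 reads drawn at random, it left a mean of 75. The ratios therefore do not measure how much RNA each antibody recovered. In an alternative, reads that shared a 3′ end and had crosslinks 1 nt apart were counted as 1 read, and clusters left with 1 position were then dropped. Together these steps left 56486 anti-Rbfox1 reads in 8920 clusters (88.0%) and 263 control reads in 109 clusters (46.8%), and raised the read ratio to 214.8. The dropping falls hardest on shallow clusters, so these values do not show the effect of the merging alone.

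As deposited, anti-Rbfox1 clusters reached greater depth. In that library 1248 clusters (12.3%, 95% interval 11.7 to 13.0) held 10 reads or more, 177 held 50 or more and 47 held 100 or more, up to 416. In the control 0 of 233 clusters reached 10 reads, which allows a share of up to 1.29%, and the highest held 9. The deep clusters held 57.3% of the anti-Rbfox1 reads, and 834 clusters were enough to hold 50% of them. Clusters of 2 reads made up 48.9% of the anti-Rbfox1 clusters (47.9 to 49.9) and 73.4% of the control clusters (67.2 to 78.9). By block of the file lines, the libraries differed most in block B, with 1275 of 4980 anti-Rbfox1 and 43 of 70 control clusters. In block A the shares were closer, with 2801 of 3634 and 106 of 130. Block C had 399 of 663 and 9 of 15, and block D 305 of 400 and 9 of 14. A draw of equal numbers of reads cannot tell whether these differences go beyond library size. At 569 reads the highest anti-Rbfox1 cluster would hold 3.65 on average, so a depth of 10 was hardly possible in a draw. With the anti-Rbfox1 library thinned to 569 reads and filtered to clusters of at least 2 positions, a mean of 75 reads in 34.4 clusters was left over 100 random draws, 0 clusters reached 10 reads in any draw, the largest held 3.91 on average (range 2 to 8), and 85.4% held 2 reads (69.7 to 100). The control's largest cluster was reached in 0 of 100 draws and its 2.44 reads per cluster in 1, while its share of clusters of 2 reads was met or exceeded in 98. The thinned reads were filtered after the draw and the control reads before deposit, so the reads left, 75 against 569, were not equal. Among the clusters of 2 reads, both reads ended at the same base and had crosslinks 1 nt apart in 21.3% in the anti-Rbfox1 library and 57.3% in the control (Fisher's exact p = 1.16e-23). The thinned anti-Rbfox1 draws gave 1.47% (0 to 10.5). Thinning rarely keeps both reads of a cluster of 2, so that value comes mainly from deeper clusters and is not comparable. The contrast differed between the blocks of file lines described further on, with 27.2% and 46.2% in block A and 9.88% and 76.7% in block B. On the minus strand of block A, where no reads share a leftmost base, such pairs cannot occur, and on its plus strand the shares were 40.6% and 59.8%. Reads shorter than 20 nt made up 9.86% of the anti-Rbfox1 reads and 18.6% of the control reads.

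**Figure D1:**
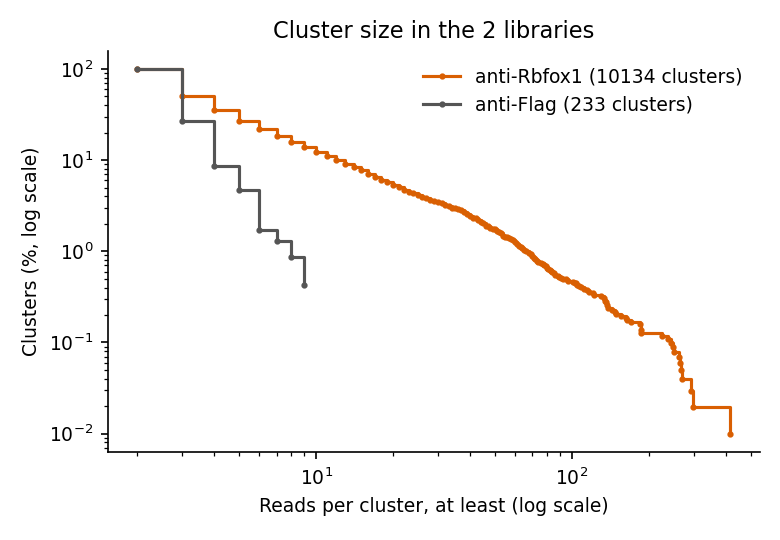
Percentage of clusters (y, log scale) that held at least the given number of reads (x, log scale) in the anti-Rbfox1 library (orange) and the anti-Flag library (grey). The control line ends at 9 reads, while the anti-Rbfox1 line reaches 416, at totals of 569 and 64820 reads.

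The highest anti-Rbfox1 cluster lay on the plus strand of chromosome 2 from 136607762 to 136608035 (mm9, as all positions here). It held 416 reads at 153 crosslink positions, 0.642% of the library (0.582 to 0.706), and 0 control reads, which allows up to 0.527% of the control. A cluster on the minus strand of chromosome 2, from 73450560 to 73450904, held 298 reads, and one on the minus strand of chromosome 7, from 17500996 to 17501177, held 292, of which 25 shared the crosslink position 17501135. On the plus strand, chromosome 8 from 56144906 to 56145077 held 269 reads. The minus strand of chromosome 5 gave a pair of the highest clusters next to each other, with 252 reads from 136384278 to 136384495 and 262 from 136384508 to 136384722. The plus strand of chromosome 12 from 101447384 to 101447601 held 245. None of these 7 clusters contained a control read.

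Control reads were present in the other 3 of the 10 highest clusters, all on the plus strand. Chromosome 11 from 17100215 to 17100377 held 268 anti-Rbfox1 and 3 control reads. Chromosome 13 from 54482586 to 54482891 held 265 and 2, and chromosome 10 from 72136937 to 72137137 held 249 and 3. At an equal share of both libraries, between 2.15 and 3.65 control reads would fall in each of the 10 clusters. The control was too small to test these clusters for a higher anti-Rbfox1 share, since even with 0 control reads the two-sided Fisher's exact p was 0.0566 for the highest and larger for the others. The 10 clusters held 4.34% of the anti-Rbfox1 reads (4.19 to 4.50). By distinct crosslink positions the 10 highest held 2.55%, and 8 clusters were among the 10 highest by both.

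Anti-Rbfox1 clusters often lay next to each other on the same strand. Of the 10134 clusters, 41.0% (40.1 to 42.0) had a neighbour within 1000 nt on the same strand and 0.138% (0.0755 to 0.232) on the opposite strand. The same-strand share was 17.3% in block A and 60.1% in block B of the file lines. The clusters formed 7297 stretches, of which 1365 had at least 2 clusters and held 72.2% of the reads, and 187 had at least 5. The stretch with most reads spanned 962 nt on the plus strand of chromosome 2 (136607185 to 136608146) and held 837 reads in 6 clusters. A stretch of 804 nt on the minus strand of chromosome 5 (136384278 to 136385081) held 791 reads in 4 clusters, and one of 997 nt on the plus strand of chromosome 8 (56144906 to 56145902) held 755 reads in 7 clusters. On the minus strand of chromosome 7, from 17500731 to 17502506, 6 clusters held 729 reads. Control reads were absent from the stretches on chromosomes 2, 5 and 7, and 2 fell in that on chromosome 8. A control cluster of 2 reads lay within 1000 nt of the chromosome 5 stretch, on the minus strand from 136385216 to 136385242.

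In the control, 3.43% of clusters (1.49 to 6.65) had a same-strand neighbour and 4 of 229 stretches had 2 clusters. When 233 anti-Rbfox1 clusters were drawn at random, a mean of 2.43% (range 0 to 6.87 over 100 draws) had one. The control's share lay within the range of these draws. The draws took clusters whatever their depth and so split up neighbours. They therefore cannot tell whether the difference between the libraries in this share goes beyond library size.

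**Figure D2:**
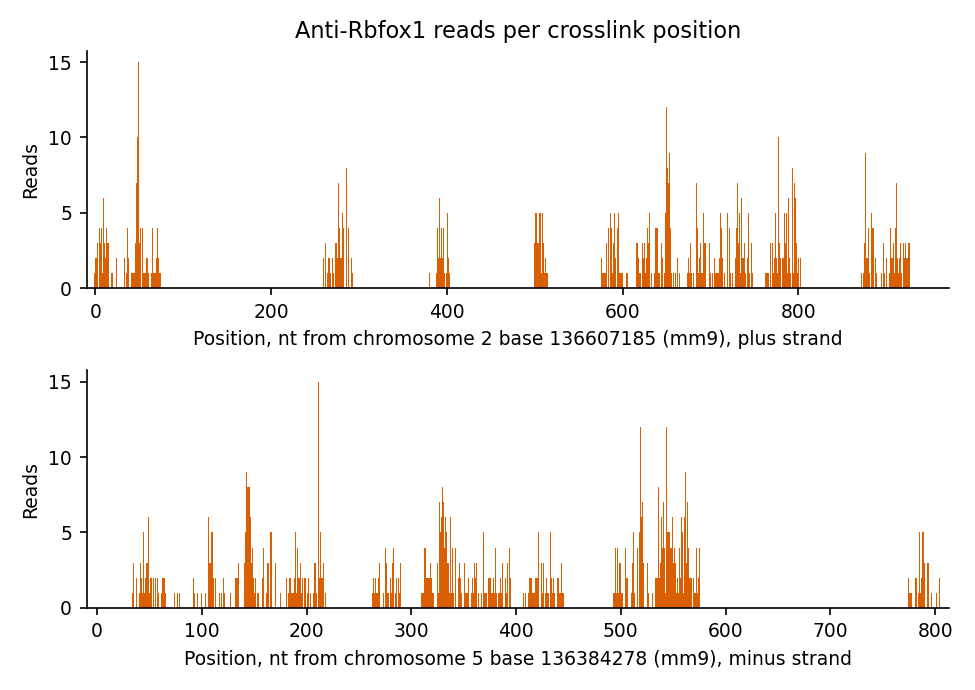
Anti-Rbfox1 reads (y) at each crosslink position (x, nt from the first base of the stretch, mm9) in the 2 stretches with most reads, on the plus strand of chromosome 2 (top, 837 reads) and the minus strand of chromosome 5 (bottom, 791 reads). Reads fall in separate groups of positions, and the highest position of each stretch holds 15.

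The highest control cluster lay on the minus strand of chromosome 13 from 97960507 to 97960585, with 9 control reads and 42 anti-Rbfox1 reads. The next, on the plus strand of chromosome 16 from 77069840 to 77069891, held 8 control reads and 0 anti-Rbfox1 reads. On the plus strand, chromosome 11 from 69858809 to 69858841 held 7 control and 4 anti-Rbfox1 reads, and chromosome 15 from 59481926 to 59481948 held 6 and 2. The remaining places among the highest were tied at 5 control reads. Among those, the cluster on the minus strand of chromosome 3 from 57646579 to 57646624 held 48 anti-Rbfox1 reads. The others held 0.

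The second comparison asked how far the signal of the 2 libraries fell at the same places. Of the control reads, 141 of 569 (24.8%, 95% interval 21.3 to 28.5) overlapped an anti-Rbfox1 read on the same strand, against a mean of 0.7 and a maximum of 6 in 100 random placements. They belonged to 53 of the 233 control clusters. From the other side, 1084 anti-Rbfox1 reads (1.67%, 1.58 to 1.77) and 58 of 10134 clusters (0.572%) overlapped control reads. Among the anti-Rbfox1 clusters of 100 reads or more, 7 of 47 overlapped control reads. They included neighbouring clusters on chromosome 11 that overlapped the same 3 control reads.

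The third comparison asked whether the libraries differed in chromosome and strand. Of the 22 tests on clusters, 0 passed an adjusted p of 0.05 and 0 an unadjusted p of 0.05 (two-sided Fisher's exact tests, Benjamini-Hochberg adjustment). The lowest adjusted p was 0.690. Chromosome 11 held 7.73% of the anti-Rbfox1 clusters (7.21 to 8.26) and 11.2% of the control clusters (7.42 to 15.9; Fisher's exact test, unadjusted p = 0.0627), and chromosome X held 4.26% and 2.15%. The mitochondrial chromosome held 5 anti-Rbfox1 reads, in 1 cluster, and 0 control reads. The plus strand held 56.8% of the anti-Rbfox1 clusters (55.8 to 57.8) and 63.1% of the control clusters (56.5 to 69.3; Fisher's exact test, unadjusted p = 0.0608). That difference of 6.28 percentage points was 10.7 without clusters within 50 nt of the other library (Fisher's exact test, unadjusted p = 0.00440). That setting removed 80 of 10134 anti-Rbfox1 clusters, and at least the 53 of 233 control clusters that overlapped. The overlap was 38.4% of control reads in block B and 19.7% in block A. The mix of blocks in the control may therefore have changed too.

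Values differed between the blocks into which the lines of both files fall. Block A held 35.9% of the anti-Rbfox1 clusters and 55.8% of the control clusters (Fisher's exact p = 1.24e-09), and block B held 49.1% and 30.04% (exact p = 5.67e-09). Block C held 6.54% and 6.44% (Fisher's exact p = 1), and block D 3.95% and 6.01% (exact p = 0.124). The anti-Rbfox1 library had 32.8 times the reads of the control in block A and 259.8 times in block B. Of the 10 highest anti-Rbfox1 clusters, all but that on chromosome 2 from 73450560, which lay in an unmatched block, were in block B. The overlap was 19.7% of control reads in block A (15.4 to 24.6) and 38.4% in block B (31.3 to 45.8). Within block A the plus strand held 65.8% of the anti-Rbfox1 and 76.2% of the control clusters (Fisher's exact p = 0.0140), and within block B 49.7% and 42.9% (p = 0.280), so the direction of the pooled strand difference did not hold in block B. After 1 read was also kept per rightmost base in block A, its plus shares were 48.9% and 45.6% (Fisher's exact p = 0.688).

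**Figure D3:**
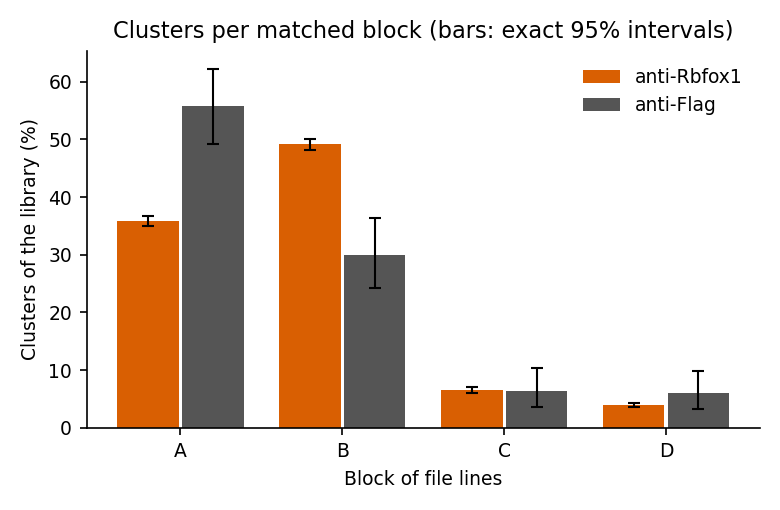
Percentage of each library's clusters (y) in the 4 blocks of file lines matched between the libraries (x), for anti-Rbfox1 (orange) and anti-Flag (grey), with exact 95% intervals as error bars. Block A holds 35.9% of the anti-Rbfox1 and 55.8% of the anti-Flag clusters, and block B 49.1% and 30.04%.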

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

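The tile numbers in the read names, which none of the comparisons used, differed in their spread between the libraries. Both libraries came from 1 lane with 96 tiles, and 81.3% of the anti-Rbfox1 reads (81.0 to 81.6) lay in the first 16 tiles, against 54.8% of the control reads (50.6 to 59.0; Fisher's exact p = 1.95e-46). The first tile alone went the other way, with 15.4% of the anti-Rbfox1 and 29.0% of the control reads. The share in the first 16 tiles was between 79.5% and 82.4% in anti-Rbfox1 clusters of every size class from 2 reads to 50 or more. The reads had been collapsed, so these shares describe the copies kept and not all reads of the lane. This comparison was chosen after the read names were seen, and no explanation, biological or technical, was tested.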

How the results depend on the processing

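Settings by block, by clusters of at least 5 reads, by neighbour distance, by merging within 50 nt and with near-identical pairs counted as 1 read were chosen after the data were seen, as were distinct positions for the read ratio and clusters for the overlap. Of 25 alternative settings, 7 left the value or call within its interval or on its side of the threshold, 14 moved a value, 2 brought a difference past an unadjusted p of 0.05 and 2 turned its direction. The ratio of anti-Rbfox1 to control, 113.9 for reads, stayed far above 1 but was 43.5 for clusters, 91.2 for positions, 719.5 for reads in clusters of at least 5 reads, 32.8 in block A, 259.8 in block B and 214.8 with reads 1 nt apart that share a 3′ end counted as 1. That last setting, which also dropped clusters left with 1 position, moved the overlap from 24.8% to 35.4% of control reads. The other overlap settings gave 22.7% to 26.4%. The plus-strand share of control clusters was 6.28 percentage points above that of anti-Rbfox1 clusters. It was 10.7 points above without clusters within 50 nt of the other library (Fisher's exact p = 0.00440) and 10.4 in block A (exact p = 0.0140), and it was -6.84 in block B (p = 0.280) and -3.26 in block A after 1 read was also kept per rightmost base (exact p = 0.688). Among clusters of at least 5 reads it was 13.8 points (Fisher's exact p = 0.386), and without the mitochondrial chromosome 6.29. Leaving out clusters near the other library may also have changed the mix of blocks in the control. The share of anti-Rbfox1 reads in the 10 highest clusters, 4.34%, was 2.55% by positions, 5.997% after merging within 50 nt and 4.02% with near-identical pairs counted as 1. The share of clusters with a same-strand neighbour, 41.0%, was 34.7% within 500 nt, 46.8% within 2000 nt, 17.3% in block A and 60.1% in block B. The cause of these differences was not tested, apart from the wider or narrower distances, which change the value by construction, and the collapse on the leftmost base in block A, weighed under the other observations. No paired analysis was possible because each antibody has 1 library. Alternatives for transcript regions by class order or measure, the motif, gene lists, positions in 3′ untranslated regions and records with a measure of at least 2 or 5 were not run. The 569 control reads limit what can be compared, since 0 reads there still allow 0.527% of the library by the limit of 3 counts and 0.646% by the exact interval.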

Other observations

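The stretches with most clusters differed from those with most reads, and were singled out after their values were seen. The stretch with most clusters lay on the minus strand of chromosome 15 (mm9, 79654393 to 79658390), with 140 reads in 24 clusters over 3998 nt. One on the minus strand of chromosome 2 (6462920 to 6467026) held 166 reads in 19 clusters, and one on the minus strand of chromosome 11 (97370782 to 97374212) 147 reads in 14. Only 14 anti-Rbfox1 clusters had a cluster on the opposite strand within 1000 nt. They lay at 5 places, on chromosomes 1, 2, 9, 11 and 19, and the deepest of them held 14 reads (chromosome 1, minus strand, 34870091 to 34870151). The single mitochondrial cluster lay on the plus strand from 11480 to 11528.

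The patterns weighed next were found in these data. The test of lane order as evidence on RNase cuts was chosen after its result was seen, and the count of near copies across libraries after that of exact copies. The bound for the test of background, a median of at most 10, was fixed beforehand, but a first way of scoring it, which asked the same of the upper quartile, left it undecided at 10.3 and was replaced by the median after that value was seen.

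The overlap of control reads with anti-Rbfox1 reads was above random placement on the genome, since 141 control reads overlapped and the highest of 100 random placements gave 6. The placements took no account of transcripts, so chance overlap among reads of the same abundant RNAs was not tested. Reads assigned to the wrong library on the shared lane stay open. Of the overlapping reads, 11.3% (6.63 to 17.8) had the start, end and strand of an anti-Rbfox1 read, against a mean of 1.68% after shifts of the positions. That share was under the bound of 20% set beforehand, but the bound missed copies that differ at an end. The same 3′ end and a 5′ end within 1 nt were found in 25.5% (18.6 to 33.6), against a mean of 4.21% after the shifts. RNA that sticks in either precipitate may also account for the overlap, since the overlapping control clusters had a median of 4.67 anti-Rbfox1 reads per control read, not the 113.9 of the whole libraries, and 0 of 53 reached 50. That test is weak, because a typical anti-Rbfox1 cluster holds 3 reads and a control cluster 2, which keeps the ratio low wherever shallow clusters meet. The overlapping places were deeper than that, with a median of 11 anti-Rbfox1 reads against 2 control reads, but still far from the depth that a ratio of 50 needs. Whether some of these places are bound by Rbfox1 as well was not tested.

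Pairs of reads with the same 3′ end and crosslinks 1 nt apart made up 57.3% of the control clusters of 2 reads and 21.3% of those in the anti-Rbfox1 library (76.7% and 9.88% in block B). Copies of one cDNA that differ at an end and so escaped the collapse are a candidate explanation: in the anti-Rbfox1 library such pairs had 1 read in the first 16 tiles and 1 later more often than other pairs (odds ratio 6.51, Fisher's exact p = 5.50e-147). If separate molecules with a preferred RNase cut were the whole cause, such pairs would be split as often as the others, on the assumption that both kinds were amplified alike, but 68.0% were split against 24.6%. A preferred cut behind part of the pairs stays open, since over all blocks the share with the same 3′ end at 1 nt was 1.89 times that at 5 to 10 nt in each library, between the bounds of 1.5 and 3 set beforehand, although in block B it was 1.61 times in the anti-Rbfox1 library and 8.04 times in the control, the latter with 11 pairs at 5 to 10 nt. Over all blocks the control share was not highest at 1 nt, with 68.7% there and 73.3% at 2 nt. In the anti-Rbfox1 library it was 14.9% and 11.6%. No biological explanation was tested.

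Block A had a plus-strand excess in both libraries, at 65.8% and 76.2% of clusters, and in this block 0 of 10007 anti-Rbfox1 reads shared their leftmost base and strand with another, while 4189 shared their rightmost base, and in block B 25155 of 48064 shared the leftmost. A collapse on the leftmost base, which is the 5′ end on the plus strand and the 3′ end on the minus strand, may account for the excess: after 1 read was also kept per rightmost base, 48.9% (46.9 to 50.9) of the anti-Rbfox1 and 45.6% (32.4 to 59.3) of the control clusters were on the plus strand. This step cannot remove minus-strand clusters, which stayed at 1245 in the anti-Rbfox1 library while plus-strand clusters went from 2390 to 1190, so the fall itself is no evidence and only the level reached, under the bound of 52% set beforehand, bears on the explanation. Collapsing block B on the leftmost base moved its plus share from 49.7% to 51.3% in the anti-Rbfox1 library and from 42.9% to 76.9% in the control. That step cannot remove plus-strand clusters, which stayed at 2476 and 30, so the rise itself is no evidence either. After both collapses the plus share of block B was 49.7% and 66.7% (46.0 to 83.5, 27 clusters). Block D resembled block A, with 74.5% and 85.7% of clusters on the plus strand and 0 of 1037 anti-Rbfox1 reads sharing their leftmost base and strand. In block C, where 538 of 2033 shared it, the plus shares were 51.9% and 33.3%. Neither block was collapsed further. No biological explanation was tested.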
